A study of Xenopus laevis with 18 samples.

How the data were processed

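RNA of dissected Xenopus laevis foreguts was measured on 18 one-colour Affymetrix arrays. Per the labels, embryos received either a mismatch control morpholino (MM) or a morpholino against the start site of rfx6 (MO1) at the 8-cell stage, and foreguts were taken at NF30, NF40 and NF44. Each of the 6 combinations of stage and morpholino was represented by 3 arrays labelled as biological replicates. Per the labels' protocols, embryos were kept in 0.1X MMR, tadpoles were anaesthetised before dissection, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. How many foreguts went into each array is not given in the sources used here.

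The table deposited by the authors holds 1 intensity per probe set and array on a linear scale, made with PLIER per the submitters' processing notes. The PLIER version, the scaling between arrays and the software settings are not given in the sources used here. Detection calls were not used here. The table holds 32635 probe sets, of which 96 control probe sets were left out and 32539 were tested. Gene symbols came from the platform's annotation table. Exactly 1 symbol was given for 15495 probe sets, several symbols for 279 and none for 16765. Of the probe sets with 1 symbol, 14870 carried a name that is not a placeholder. Gene identifiers of 15384 were found in a table of RefSeq genes of the Xenopus laevis v10.1 assembly, which updated 2 symbols. The suffixes .L and .S denote the gene copies on the long and short chromosomes of this allotetraploid species, and nearly identical copies can cross-hybridise. No probe set was named rfx6, pdx1 or neurog3, so these genes were not analysed here.

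The groups, the comparisons, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. Intensities were taken as log2 of the value plus 16, and all log2 changes are on that scale, which understates changes of dim genes. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 18 arrays with 1 coefficient per group, which left 12 residual degrees of freedom. MO1 was compared with MM at each stage and as the mean over the 3 stages, the differences of the MO1 effect between stages were tested as interaction contrasts, and MM arrays of successive stages were compared. P-values were adjusted by Benjamini-Hochberg over all tested probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. The array number of 3 per group limits precision, and an exact permutation test of 3 against 3 arrays cannot go below p = 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

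For every single-stage MO1 contrast and for the mean over stages, the genes eligible for naming were the 10 largest falls and the 10 largest rises among probe sets with 1 symbol that is not a placeholder and an adjusted p under 0.05. For a single stage all 3 MO1 arrays also had to lie on one side of all 3 MM arrays. In the interaction and MM stage contrasts 5 genes in each direction were eligible. From each gene list up to 4 members with the smallest p-values could be named. A gene with several probe sets was named from the one with the largest change, or from its brightest one where it came from a list, and its other probe sets can differ.

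The 23 fixed lists covered the Rfx family, endocrine transcription factors, islet and gut hormones, endocrine secretory machinery, exocrine pancreas enzymes, exocrine and pancreas progenitor transcription factors, liver, intestine, stomach and lung, gut mesenchyme and smooth muscle, skeletal muscle, heart, blood, neural, epidermis, kidney, notochord and cartilage, p53 response, interferon and innate immunity, cell cycle, Notch, retinoic acid and Hedgehog. Each gene entered with its brightest probe set. Members called over all tested probe sets were counted, and members called when p-values were adjusted over the list alone were counted beside them. A shift of a list against all other genes was tested with limma camera at its preset correlation of 0.01, adjusted over the lists of a contrast. Synonyms that name another gene were left out of the lists. A further 6 lists (motile cilia, ionocyte proton pump, FoxO targets, glucocorticoid response, integrated stress response, gluconeogenesis and related) were written after the data had been examined.

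Replicate numbers were tested for pairing by correlating residuals of MM and MO1 arrays with the same number within a stage. The correlations were 0.41, 0.38 and 0.49 at NF30, 0.41, 0.21 and 0.40 at NF40, and 0.15, 0.43 and 0.35 at NF44, so arrays with the same number resembled each other. MM arrays with the same number at successive stages were mostly less alike. Their residual correlations were 0.23, -0.12 and 0.09 for NF30 with NF40 and 0.05, -0.05 and -0.03 for NF40 with NF44. The 0.23 of replicate 1 lay above the lowest correlations within a stage, 0.21 and 0.15. Fits with the replicate number as a block were run as alternatives.

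The fit was tested on simulated data in which 200 of 32539 probe sets were changed. Changes of 1 on the log2 scale were recovered for 77 to 89 percent of changed probe sets in the 5 contrasts simulated, and changes of 2 for 92 to 97 percent, with 7 to 9 false calls. A shift of 1 given to the exocrine list was called by camera in the simulated data, and no other list was called. The simulated noise was independent between probe sets and arrays. The simulation therefore does not show how often camera calls lists wrongly where genes are correlated. Alternatives covered a pseudocount of 1, a floor at the 25th percentile, leaving out the dimmer 50 percent of probe sets, quantile normalization and median centring, eBayes with trend and robust options, array weights, fits of the compared arrays alone, replicate blocks, a change of at least 1 on the log2 scale, leaving out probe sets ending in _s_at or _x_at, and leaving out each array in turn. For lists the alternatives were camera with an estimated correlation, fry, and the mean of all probe sets of a gene.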

Results

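Foreguts of Xenopus laevis carrying the control morpholino MM or the rfx6 start-site morpholino MO1 were compared at NF30, NF40 and NF44 on 18 arrays, 3 biological replicates per group. A start-site morpholino blocks translation, so the targeted mRNA need not fall. The median intensity of an array lay between 82.2 and 100 and the mean between 367 and 426, with the lowest values of both on the first MO1 array at NF44. The 10 brightest probe sets held 2.79 ± 0.17 percent of the signal in MM foreguts at NF44 and 1.60 ± 0.03 percent in MO1 foreguts (mean ± SD of 3 arrays). Correlations between log2 profiles were 0.974 to 0.989 within a group, 0.928 to 0.983 between morpholinos at a stage, and 0.825 to 0.951 between stages. The first principal component held 54.6 percent of the variance, the second 14.4 percent and the third 8.30 percent. In the text below, levels are mean intensity ± SD of 3 arrays and changes are log2 changes ± SE.

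Control foreguts were followed first, since they set the baseline for the knockdown. From NF30 to NF40 the largest rises were in genes of absorption and of the liver. Rbp2 binds retinol in enterocytes, fabp2 carries fatty acids, and fgb encodes the beta chain of fibrinogen. Rbp2.L rose from 32.6 ± 9.11 to 7770 ± 359 (7.34 ± 0.32, limma adjusted p = 2.2e-10), and fabp2.S rose from 3.84 ± 3.95 to 2380 ± 127. The lipoprotein genes apoa4.S and apoa4.L and the fibrinogen gene fgb.L rose by 6.64, 6.56 and 6.39. The largest fall was that of the astacin protease gene astl2d.1.L, which changed by -6.16 ± 0.23 (limma adjusted p = 4.2e-11), and other large falls were those of the protease gene tll2l.L (-4.94, and -1.48 at a further probe set), the keratin gene krt70.L (-4.80), the histidine ammonia-lyase gene hal.1.L (-4.62), which is on the liver list, and krt70.S (-4.3). For each of these genes all 3 NF40 arrays lay on one side of all 3 NF30 arrays.

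Of 46 liver genes, 40 rose and 1 fell between NF30 and NF40 in MM foreguts (41 and 2 when adjusted over the list alone). Fgb.L, the urate oxidase gene uox.L (5.98), the protein C gene proc.S (4.19) and the prothrombin gene f2.S (3.09) led that list. Its median change was 2.38, with a limma camera adjusted p of 9.7e-20, and adjusted p = 0.092 with an estimated correlation. Exocrine enzyme genes began to appear at this step, with 7 of 24 higher and 1 lower (9 and 1 over the list alone; camera adjusted p = 0.0052, adjusted p = 0.36 with an estimated correlation). Among them pdia2.L rose by 4.62 and ctrc.L by 4.04. In the stomach and lung list 8 of 20 genes rose and 1 fell (8 and 1 alone), including the surfactant gene sftpc.S (4.91), tff3.2.S (4.61) and the lung and thyroid regulator nkx2-1.L (3.90); its camera adjusted p was 0.0067 (adjusted p = 0.20 with an estimated correlation). Insulin (ins.L) rose from 97 ± 34.3 to 537 ± 111 and the acinar regulator ptf1a from 23.8 ± 12.5 to 207 ± 34.4. Epidermal genes went the other way, with 19 of 25 lower and 1 higher (19 and 1 alone), a median of -1.29 and a camera adjusted p of 9.9e-07, adjusted p = 0.20 with an estimated correlation. In all, 4593 probe sets were higher and 6119 lower at NF40.

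Genes of pancreatic proteases and of the gastric proton pump were among the largest rises in MM foreguts from NF40 to NF44. Cela1.5, ctrl and cela2a encode pancreatic serine proteases, atp4a and atp4b the subunits of the gastric proton pump, and pglyrp1 a peptidoglycan-binding protein. Ctrl.L rose from 583 ± 401 to 182000 ± 9040, cela1.5.L from 19.5 ± 3.46 to 16800 ± 2950 (8.88 ± 0.12, limma adjusted p = 9.7e-17) and pglyrp1.S from 31.1 ± 3.14 to 41400 ± 4910. The pump genes atp4b.L and atp4a.S rose by 9.12 ± 0.82 and 8.43 ± 0.52. Falls were led by the keratin gene krt12.4.S, from 7830 ± 4880 to 31.1 ± 12.1, and included itln1.L (-5.94), darmin.L (-5.87, and -4.15 at a further probe set) and the glucose-6-phosphatase gene g6pc1.2.S (-5.22). All 3 NF44 arrays lay on one side of all 3 NF40 arrays for each gene.

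In this step 17 of 24 exocrine enzyme genes rose and 1 fell (18 and 1 alone), with a median of 3.47, a camera adjusted p of 1.2e-12 and an adjusted p of 0.017 with an estimated correlation. Islet and gut hormone genes followed: 10 of 13 rose and none fell (12 and 0 alone), the median was 1.64 and the camera adjusted p was 9e-08 (0.009 with an estimated correlation, and 0.082, no call, without the dimmer 50 percent of probe sets). Somatostatin (sst.1.S) rose from 26.2 ± 3.10 to 2120 ± 300 and glucagon (gcg.L) from 6.43 ± 3.57 to 221 ± 45.9. The secretory granule genes scg3.L and chga.L rose by 2.29 and 2.18 (0.25 at a further chga.L probe set), and 13 of the 18 secretory genes rose while 1 fell (13 and 1 alone; camera adjusted p = 0.00053, adjusted p = 0.10 with an estimated correlation). Proliferation genes declined, with 23 of 37 cell cycle genes lower and none higher (25 and 0 alone; median -0.54, camera adjusted p = 5.5e-06, adjusted p = 0.42 with an estimated correlation). In all, 5511 probe sets were higher and 6052 lower at NF44 than at NF40.

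At NF30 insulin and several transcription factor genes of endocrine precursors were lower in MO1 foreguts, although neither the hormone list nor the endocrine factor list was shifted. Insulin is made by beta cells, neurod1 and insm1 are transcription factors of endocrine precursors, and foxa2 and sox9 are regulators of foregut endoderm and pancreatic progenitors. Ins.L (probe set Xl2.23623.1.S1_at) fell from 97 ± 34.3 in MM to 13.5 ± 4.32 in MO1 (-1.91 ± 0.32, limma adjusted p = 0.0022). Neurod1.S fell from 91.1 ± 23.5 to 27.7 ± 14 (-1.32 ± 0.21, adjusted p = 0.0019), neurod1.L fell by 1.07 on the log2 scale and insm1.L fell by 0.64, whereas a further probe set of insm1.L gave 0.12. Endocrine transcription factors as a list were not shifted, with 2 of 15 higher and 4 lower (2 and 5 alone) and a camera adjusted p of 0.67. Nkx6-2.L, on that list, rose from 29.6 ± 8.12 to 56.3 ± 8.76 (0.675 ± 0.16, limma adjusted p = 0.013). Among hormones 2 of 13 were lower and none higher (2 and 0 alone), and the camera adjusted p was 0.82 with a mean change of -0.13 but a median of 0.10. Foxa2.L and sox9.L fell by 0.97 and 0.86 on the log2 scale (a further foxa2.L probe set gave -0.27), while nr5a2.L rose by 0.92, and 3 of 27 progenitor transcription factors were higher and 2 lower (4 and 3 alone; camera adjusted p = 0.33). None of 24 exocrine enzyme genes differed, nor did any when adjusted over the list alone (camera adjusted p = 0.67). For each gene named here all 3 MO1 arrays lay on one side of all 3 MM arrays.

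The largest falls at NF30 were in genes of the heart. Tnni3, mylc2a, myh6, myl4 and tnnc1 encode contractile proteins of cardiac muscle, and tbx5 and nkx2-5 are cardiac regulators. Tnni3.S fell from 344 ± 83.3 to 40.5 ± 37.1 (-2.97 ± 0.48, limma adjusted p = 0.0018), mylc2a from 499 ± 164 to 59.0 ± 45.2 (-2.93 ± 0.38, adjusted p = 0.00042, and -2.93 to -1.13 over its 5 probe sets) and myh6.S from 583 ± 286 to 72.8 ± 39.4. Myl4.L and tnnc1.L changed by -2.67 and -2.14. Of 16 heart genes 9 fell and none rose (9 and 1 alone), with a median of -0.89 and a camera adjusted p of 0.00069, adjusted p = 0.73 with an estimated correlation. In the gut mesenchyme list 3 of 27 genes rose and 3 fell (3 and 4 alone; camera adjusted p = 0.98), with hand1.L higher by 1.13 and tbx5.L and nkx2-5.S lower by -1.08 and -1.11. Skeletal muscle moved in the opposite direction to the heart: the median of 23 genes was 0.999 and the camera adjusted p 0.00069, adjusted p = 0.92 with an estimated correlation, although only 1 gene was called higher (11 alone, none lower). The skeletal muscle level differed widely among the MM arrays at NF30, with a mean log2 level of 7.25 ± 1.40 in MM against 8.53 ± 0.09 in MO1. The muscle ankyrin repeat gene ankrd2.S had the largest rise among called genes with a symbol (2.73 ± 0.76, adjusted p = 0.033), and its call was lost without MM replicate 2 (adjusted p = 0.12), MM replicate 3 (0.14), MO1 replicate 1 (0.099), MO1 replicate 2 (0.062) or MO1 replicate 3 (0.07). The troponin gene tnni1.2.L (2.45, adjusted p = 0.043) and the phosphoglycerate mutase gene pgam2.L (2.26, adjusted p = 0.016) were also among the largest rises. The call of tnni1.2.L was lost without MM replicate 2 (0.082), MM replicate 3 (0.18), MO1 replicate 1 (0.11), MO1 replicate 2 (0.075) or MO1 replicate 3 (0.1), and that of pgam2.L without MM replicate 3 (0.066), MO1 replicate 1 (0.051) or MO1 replicate 3 (0.061).

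Replication and p53 target genes also changed at NF30. The arrays hold 1 morpholino against rfx6 and no rescue, and rfx6 itself was not analysed. Effects of losing rfx6 therefore cannot be told apart from other effects of the morpholino, here and at the later stages. Mcm4 is a subunit of the replicative helicase, mki67 marks dividing cells, donson acts at replication forks and mthfd1 supplies one-carbon units for nucleotide synthesis. Donson.L fell from 907 ± 87.9 to 310 ± 80.3 (-1.53 ± 0.17, limma adjusted p = 0.00019) and mthfd1.L from 161 ± 34.5 to 35.5 ± 9.11 (-1.78 ± 0.18, adjusted p = 7.7e-05), though a further mthfd1.L probe set gave -0.18. Mcm4.S, mcm4.L and mki67.S changed by -1.08, -0.81 and -0.80, and the 4 probe sets of mki67.S ranged from -0.80 to -0.40. Of 37 cell cycle genes 19 fell and none rose (24 and 0 alone), with a median of -0.53 and a camera adjusted p of 1.6e-11, adjusted p = 0.51 with an estimated correlation. Sestrins and ccng1 are p53 target genes. Sesn1.L rose from 137 ± 18.8 to 575 ± 69.8 (1.95 ± 0.14, adjusted p = 1.6e-06), ccng1.L from 4740 ± 553 to 9590 ± 451 and plk2.L from 130 ± 16.9 to 241 ± 18.7. In the p53 response list 10 of 21 genes rose and 1 fell (12 and 1 alone), the median was 0.55 and the camera adjusted p was 2.4e-06 (0.026 with an estimated correlation). Each named gene separated all 3 MO1 arrays from all 3 MM arrays.

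Muscle genes apart, the largest rises at NF30 included cxcl12.L, pck1.L and thbs4.S. Cxcl12 encodes a chemokine that guides migrating cells, thbs4 a matrix protein, pck1 phosphoenolpyruvate carboxykinase and g6pc1.1 glucose-6-phosphatase. Cxcl12.L rose from 165 ± 76.6 to 1050 ± 326 (2.6 ± 0.25, limma adjusted p = 4.3e-05). Pck1.L rose from 525 ± 65.3 to 2510 ± 736, g6pc1.1.L from 1690 ± 770 to 6570 ± 1930 and thbs4.S from 58.2 ± 42.8 to 283 ± 54.5. Epidermal genes were shifted up, with 3 of 25 higher and none lower (3 and 0 alone), a median of 0.31 and a camera adjusted p of 0.0013, adjusted p = 0.73 with an estimated correlation; krt8.1.S rose by 0.55. The intestinal regulator cdx4.L rose by 1.25, and 3 of 22 intestinal genes rose and 1 fell (5 and 1 alone; camera adjusted p = 0.14). In the liver list 2 of 46 genes rose and 1 fell (0 and 1 alone; camera adjusted p = 0.67). In all, 1446 probe sets were higher and 1765 lower at NF30, which is 9.87 percent of those tested, and 323 of them changed by at least 1. The total of 3211 was 1048 when only the compared arrays were fitted, 1699 without MM replicate 3, 1849 without MO1 replicate 1 and 2032 without MO1 replicate 3.

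**Figure D1:**
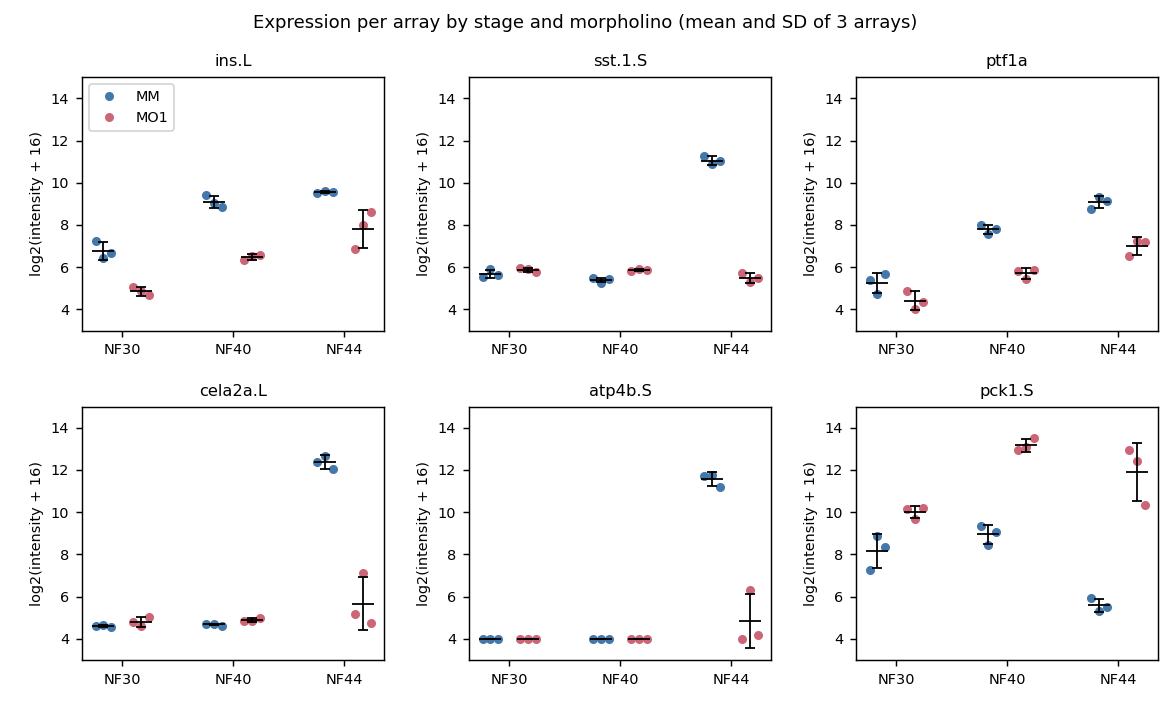
Expression of 6 genes as log2(intensity + 16) on the vertical axis, by stage and morpholino, with 1 point per array and bars for mean and SD of 3 arrays. Ins.L and ptf1a were lower in MO1 at NF40 (-2.61 and -2.08), sst.1.S, cela2a.L and atp4b.S were lower at NF44 (-5.56, -6.70 and -6.72), and pck1.S was higher at NF40 and NF44 (4.22 and 6.31).

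At NF40 several genes of pancreas, stomach and lung were low in MO1 foreguts. Tff3.2 is a secreted trefoil peptide, pdia2 a protein disulfide isomerase of acinar cells, ctse an aspartic protease of the stomach, sftpc a surfactant protein of the lung and cldn18 a tight junction protein of lung and stomach. Tff3.2.S was at 546 ± 163 in MM and 5.87 ± 2.49 in MO1 (-4.65 ± 0.26, limma adjusted p = 5.1e-08), pdia2.L at 383 ± 68.5 and 6.94 ± 3.85 (-4.12 ± 0.23, adjusted p = 5.1e-08) and ctse.L at 2710 ± 530 and 151 ± 34.1. Sftpc.S and cldn18.L changed by -3.95 and -3.91. The enzyme genes cel.2.S, cela1.1.S, ctrc.L and ca6.L fell by 3.78, 3.41, 3.40 and 3.15 on the log2 scale. In the stomach and lung list 7 of 20 genes fell and 1 rose (7 and 1 alone), with a median of -0.39 and a camera adjusted p of 0.0020, adjusted p = 0.17 with an estimated correlation. Nkx2-1.L, on that list, fell from 239 ± 55.0 to 23.6 ± 20.7. Of 24 exocrine enzyme genes 6 fell and 1 rose (6 and 1 alone; camera adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation). All 3 MO1 arrays lay on one side of all 3 MM arrays for each gene.

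Several regulator genes of pancreas and endocrine cells fell at NF40, although the endocrine factors were not shifted as a list when dim probe sets were kept. Ptf1a specifies acinar cells, gata6 and prox1 act in pancreas and liver progenitors, and nkx6-2 and mnx1 are homeobox genes of the endocrine pancreas. Ptf1a fell from 207 ± 34.4 to 36.8 ± 8.74 (-2.08 ± 0.27, limma adjusted p = 0.00013), foxa2.L changed by -2.17 ± 0.18, and gata6.L and prox1.L by -1.12 and -1.11. Of 27 progenitor transcription factors 12 fell and none rose (12 and 0 alone), with a median of -0.49 and a camera adjusted p of 7.2e-06, adjusted p = 0.17 with an estimated correlation. Nkx6-2.L fell from 498 ± 33.3 to 51.7 ± 5.98 (-2.93 ± 0.16, adjusted p = 4.7e-08, and -0.43 at a further probe set), and mnx1.L and mnx1.S fell by 2.01 and 1.83 on the log2 scale. Endocrine transcription factors had 2 of 15 higher and 5 lower (3 and 5 alone), and camera gave an adjusted p of 0.30; the mean was -0.38 while the median was 0.02. Insulin fell at both copies, ins.L from 537 ± 111 to 73.9 ± 8.55 and ins.S from 599 ± 156 to 82.8 ± 12.9, whereas sst.1.L rose from 74.0 ± 3.36 to 219 ± 29.1. Among 13 hormone genes 4 rose and 3 fell (4 and 3 alone; camera adjusted p = 0.63, with a mean of -0.09 and a median of 0.08). The secretory machinery list had 3 of 18 genes higher and 1 lower (3 and 1 alone; camera adjusted p = 0.62). Every gene named separated the 3 MO1 arrays from the 3 MM arrays.

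Ucp1.S, sds.S and pck1.L were among the largest rises at NF40. Ucp1 encodes an uncoupling protein, sds serine dehydratase, eno3 an enolase, and pck1 and g6pc1 the first committed and the last enzyme of gluconeogenesis. Ucp1.S rose from 4.2 ± 3.96 to 691 ± 135 (5.13 ± 0.30, limma adjusted p = 6.3e-08), pck1.S from 493 ± 154 to 9260 ± 1970 (4.22 ± 0.51, adjusted p = 8.6e-05) and g6pc1.1.L from 378 ± 114 to 7080 ± 860. Pck1.L, sds.S, eno3.L and sds.L rose by 4.32, 4.48, 4.25 and 3.72, and the 3 probe sets of sds.S ranged from 1.87 to 4.48. The liver list as such was not shifted, with 5 of 46 genes higher and 9 lower (5 and 14 alone; camera adjusted p = 0.21). Intestinal genes had 1 of 22 higher and 3 lower (1 and 3 alone; camera adjusted p = 0.69). The p53 response stayed up, with 9 of 21 genes higher and none lower (10 and 1 alone), a median of 0.43 and a camera adjusted p of 0.00014, adjusted p = 0.12 with an estimated correlation; sesn1.L rose by 2.71 and sesn2.S by 1.35. Cell cycle genes stayed down, with 15 of 37 lower and none higher (23 and 0 alone), a median of -0.37 and a camera adjusted p of 6.1e-06, adjusted p = 0.46 with an estimated correlation. All 3 MO1 arrays lay above all 3 MM arrays for each gene that rose.

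Other tissues represented in the dissected foregut also shifted at NF40. Upk3a and upk1b encode uroplakins of surface epithelia, grhl3 is an epidermal regulator, alas2 makes heme in red cells, and nefm is a neurofilament. Upk3a.L rose from 346 ± 157 to 1470 ± 331 (2.1 ± 0.32, limma adjusted p = 5e-04), upk1b.L by 1.77 and grhl3.S by 1.51, with 13 of 25 epidermal genes higher and 1 lower (16 and 1 alone; median 0.53, camera adjusted p = 2e-06, adjusted p = 0.17 with an estimated correlation). Heart genes had 12 of 16 lower and none higher (12 and 0 alone), with a median of -1.13 and a camera adjusted p of 5.4e-06, adjusted p = 0.17 with an estimated correlation; myl3.S fell from 320 ± 143 to 13.5 ± 7.28. Blood genes had 9 of 24 higher and none lower (13 and 0 alone; camera adjusted p = 1.7e-05, adjusted p = 0.31 with an estimated correlation), among them alas2.L (1.24). Neural genes had 9 of 25 higher and 1 lower (14 and 2 alone; camera adjusted p = 0.00042, adjusted p = 0.46 with an estimated correlation), among them nefm.L (1.93). The mean log2 level of the neural list was 7.25, 6.55 and 7.14 in MO1 replicates 1, 2 and 3. In MM it was 6.30, 6.55 and 6.42, so MO1 replicate 2 showed no rise over MM replicate 2. In the interferon and innate immunity list 3 of 27 were higher (3 alone, none lower; camera adjusted p = 0.00084, adjusted p = 0.47 with an estimated correlation), among them psmb8.L (1.13). Skeletal muscle had 1 of 23 higher and 2 lower (0 and 2 alone; median 1.29, camera adjusted p = 0.26), with myog.S lower by -1.66 and mean log2 levels of 8.69 ± 0.45 in MM and 9.46 ± 0.50 in MO1. Gut mesenchyme genes had 2 of 27 higher and 7 lower (6 and 8 alone; camera adjusted p = 0.40). Each named gene had all 3 MO1 arrays on one side of all 3 MM arrays.

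At NF40 3025 probe sets were higher and 2524 lower in MO1, which is 17.1 percent of those tested. Of these, 1133 were higher and 240 lower by at least 1 on the log2 scale. Scaling mattered for the split: under median centring 2826 were higher and 4295 lower, so the share of higher calls was 39.7 percent in place of 54.5 percent. The total of 5549 was 3361 without MM replicate 2 and 3057 without MO1 replicate 3.

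By NF44 the digestive enzymes and the gastric proton pump were far below the MM levels in MO1 foreguts. Cela1.5, ctrl and prss2 encode pancreatic proteases, amy2b and amy2a amylases, cpb1 a carboxypeptidase and lgals4.1 a galectin of the gut lining. Cela1.5.L was at 16800 ± 2950 in MM and 34.4 ± 4.3 in MO1 (-8.37 ± 0.12, limma adjusted p = 2.4e-16). Ctrl.L, the brightest of them, was at 182000 ± 9040 and 2780 ± 3880 (-7.34 ± 0.87, adjusted p = 1.2e-05), and prss2.L at 14700 ± 329 and 354 ± 449. Cela2a.L, amy2b.S, cpb1.S and amy2a.L changed by -6.70, -6.03, -5.80 and -5.32, and the 3 probe sets of cpb1.S ranged from -5.80 to -1.80. Of 24 exocrine enzyme genes 18 fell and none rose (19 and 0 alone), with a median of -3.25, a camera adjusted p of 5e-12 and an adjusted p of 0.013 with an estimated correlation. Atp4b.L fell from 24600 ± 7520 to 355 ± 573 and atp4b.S from 3040 ± 643 to 22 ± 36.2, and the stomach and lung list had 10 of 20 genes lower and 3 higher (10 and 3 alone; median -0.70, camera adjusted p = 0.025, adjusted p = 0.26 with an estimated correlation). Pglyrp1.S fell from 41400 ± 4910 to 282 ± 408, and the sulfotransferase gene sult6b1l.L by 5.90 on the log2 scale (-2.69 at a further probe set). The SD of several of these genes in MO1 was as large as their mean, yet all 3 MO1 arrays lay below all 3 MM arrays for each.

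Hormone genes fell alongside the enzymes at NF44. Sst.1 encodes somatostatin, gcg glucagon, nts neurotensin, and chga and scg3 are granins of secretory granules. Sst.1.S fell from 2120 ± 300 to 29.5 ± 7.07 (-5.56 ± 0.13, limma adjusted p = 1.3e-13), gcg.L from 221 ± 45.9 to 26.2 ± 5.97 (-2.48 ± 0.18, adjusted p = 7.6e-08) and nts.S from 93.4 ± 21.3 to 11.3 ± 6.53. Of 13 hormone genes 9 fell and none rose (9 and 0 alone), with a median of -1.76, a camera adjusted p of 6.4e-06 and an adjusted p of 0.013 with an estimated correlation. Chga.L and scg3.L changed by -1.84 and -1.34 (-0.20 at a further chga.L probe set), and 8 of 18 secretory genes fell while none rose (9 and 0 alone; camera adjusted p = 0.0074, adjusted p = 0.26 with an estimated correlation). Endocrine transcription factors had 1 of 15 higher and 6 lower (2 and 6 alone), among them nkx6-2.L (-2.14), insm1.L (-1.14), neurod1.S (-1.05) and pax6.L (-0.85), but camera gave an adjusted p of 0.12. A further probe set gave -0.61 for nkx6-2.L and 0.03 for insm1.L, and the 3 of pax6.L ranged from -2.07 to -0.04. Progenitor transcription factors split, with 9 of 27 higher and 9 lower (9 and 10 alone; camera adjusted p = 0.47, with a mean of -0.03 and a median of 0.10). Ptf1a fell from 534 ± 104 to 115 ± 34.2 and foxa2.L from 533 ± 32.8 to 181 ± 38.2. Of the 3 Rfx family genes measured, 1 was higher and 1 lower (1 and 2 alone; camera adjusted p = 0.82), and none was called at NF30 or NF40. Each gene named separated all 3 MO1 arrays from all 3 MM arrays.

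The largest rises at NF44 included pck1.S, ucp1.S and g6pc1.2.S. A rise here is a difference from MM at the same stage. G6pc1.2.S itself fell in MM, from 1400 ± 230 at NF40 to 21.7 ± 1.82 at NF44. Cfb encodes complement factor B, mmp1 a collagenase, acod1lb a relative of the itaconate-producing enzyme, apoa4 an intestinal apolipoprotein and ass1 argininosuccinate synthase. Pck1.S rose from 32.6 ± 10.5 to 4850 ± 3340 (6.31 ± 0.51, limma adjusted p = 2.1e-07), ucp1.S from 6.49 ± 4.62 to 1380 ± 649 (5.85 ± 0.30, adjusted p = 1.5e-09) and cfb.S from 37.5 ± 4.72 to 1080 ± 119. G6pc1.2.S, mmp1.S, ucp1.L, acod1lb.L and adh7.S rose by 5.79, 4.87, 4.72, 4.1 and 3.92, and the 3 probe sets of acod1lb.L ranged from 0.07 to 4.1. In the liver list 12 of 46 genes rose and 12 fell (14 and 13 alone; camera adjusted p = 0.12), with ass1.S higher by 3.69. In the intestine list 9 of 22 rose and 4 fell (9 and 5 alone; median 0.37, camera adjusted p = 0.035, adjusted p = 0.43 with an estimated correlation), with apoa4.S up from 641 ± 324 to 8080 ± 729 and lgals4.1.s down from 5070 ± 392 to 115 ± 65.1. The interferon and innate immunity list had 5 of 27 higher and none lower (5 and 0 alone; camera adjusted p = 0.0016, adjusted p = 0.45 with an estimated correlation). All 3 MO1 arrays lay on one side of all 3 MM arrays for each gene.

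Among the signalling and stress lists at NF44, p53 response and retinoic acid genes were shifted up under both camera settings. Crabp2 binds retinoic acid and rdh5 oxidises retinol. Rdh5.L rose from 26.9 ± 6.02 to 104 ± 13.9 (1.48 ± 0.19, limma adjusted p = 2.3e-05). Crabp2.L was at 35.3 ± 3.81 in MM and 299 ± 68.4 in MO1 at its listed probe set (2.6 ± 0.15, adjusted p = 6.7e-09), but its 5 probe sets ranged from -0.78 to 2.6, with calls in both directions. In this list 8 of 18 genes were higher and none lower (9 and 1 alone; median 0.45, camera adjusted p = 0.00016, and 0.013 with an estimated correlation). Of 21 p53 response genes 11 rose and none fell (13 and 0 alone), with a median of 0.55, a camera adjusted p of 1.8e-05 and an adjusted p of 0.013 with an estimated correlation; sesn2.L and sesn1.L rose by 2.06 and 1.81. Notch genes had 7 of 17 higher and 1 lower (8 and 1 alone; camera adjusted p = 0.012, adjusted p = 0.43 with an estimated correlation). Hedgehog genes had 3 of 15 higher and none lower (3 and 0 alone; camera adjusted p = 0.035, adjusted p = 0.13 with an estimated correlation). Cell cycle genes had 11 of 37 lower and none higher (14 and 0 alone; median -0.20, camera adjusted p = 0.035, adjusted p = 0.66 with an estimated correlation).

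Among the tissue lists at NF44, notochord and cartilage genes had 5 of 15 higher and none lower (5 and 0 alone; camera adjusted p = 0.0028, adjusted p = 0.26 with an estimated correlation). Kidney genes had 5 of 14 higher and none lower (6 and 0 alone; camera adjusted p = 0.035, adjusted p = 0.26 with an estimated correlation). Neural genes had 5 of 25 higher and 1 lower (5 and 1 alone; camera adjusted p = 0.0097, adjusted p = 0.46 with an estimated correlation). Skeletal muscle genes had 4 of 23 higher and 1 lower (4 and 1 alone; median 1.11, camera adjusted p = 0.0028, adjusted p = 0.47 with an estimated correlation), and their mean log2 level was 7.75 ± 0.56 in MM and 8.74 ± 0.84 in MO1. Heart genes had 3 of 16 higher and 2 lower (4 and 2 alone; camera adjusted p = 0.34, with a mean of -0.05 and a median of 0.15); the light chain gene myl3.S fell from 999 ± 146 to 135 ± 70.4 while the natriuretic peptide gene nppa.L rose from 771 ± 224 to 2220 ± 272. Gut mesenchyme genes had 7 of 27 higher and 8 lower (8 and 10 alone; camera adjusted p = 0.42, with a mean of -0.11 and a median of 0.07), among them hand1.L (1.77) and the smooth muscle gene cnn1.S (-1.44). Blood genes had 6 of 24 higher and 2 lower (7 and 2 alone); camera gave an adjusted p of 0.12 in the upward direction, the mean was 0.24 and the median -0.03. Epidermal genes had 7 of 25 higher and 1 lower (7 and 2 alone; camera adjusted p = 0.066, and 0.048 with replicates as a block within stages). In all, 3526 probe sets were higher and 4855 lower at NF44, which is 25.8 percent of those tested, and 2183 changed by at least 1.

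**Figure D2:**
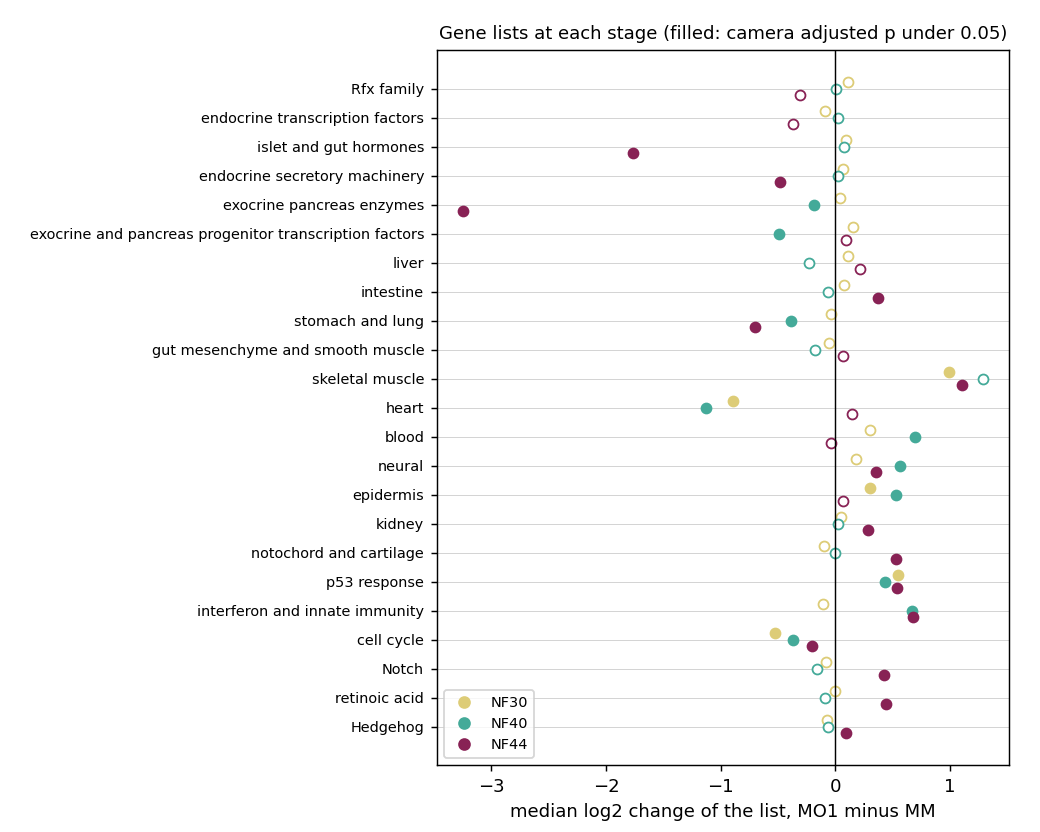
Median log2 change of each gene list (MO1 minus MM, horizontal axis) at NF30, NF40 and NF44, with 1 point per list and stage, filled where limma camera gave an adjusted p under 0.05. Exocrine enzymes reached -3.25 and hormones -1.76 at NF44, while heart genes were lowest at NF40 (-1.13).

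Averaged over the 3 stages, tff3.2.S had the largest fall and pck1.S the largest rise. Tff3.2.S changed by -3.35 ± 0.15 (limma adjusted p = 1.1e-09), ctrl.L by -3.18 and cela1.1.S by -2.90, while pck1.S rose by 4.13 ± 0.30 (adjusted p = 1.3e-07), ucp1.S by 3.74 and pck1.L by 3.64. Both insulin copies were lower, ins.S by -2.15 and ins.L by -2.09, as were sst.1.S (-1.63) and gcg.L (-0.77). The fall of sst.1.S came from NF44. At NF40 its log2 values were 5.81 to 5.93 in MO1, above the 5.27 to 5.48 in MM. Of 13 hormone genes 7 were lower and none higher (7 and 0 alone; camera adjusted p = 0.0036, adjusted p = 0.12 with an estimated correlation). Of 15 endocrine transcription factors 8 were lower and 2 higher (9 and 2 alone; camera adjusted p = 0.058). The p53 response had 14 of 21 genes higher and 1 lower (15 and 1 alone; camera adjusted p = 3.5e-07, and 0.015 with an estimated correlation), and sesn1.L rose by 2.11. Cell cycle genes had 27 of 37 lower and none higher (28 and 0 alone; camera adjusted p = 3.6e-07, adjusted p = 0.33 with an estimated correlation). Over all probe sets 4768 were higher and 5952 lower.

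**Figure D3:**
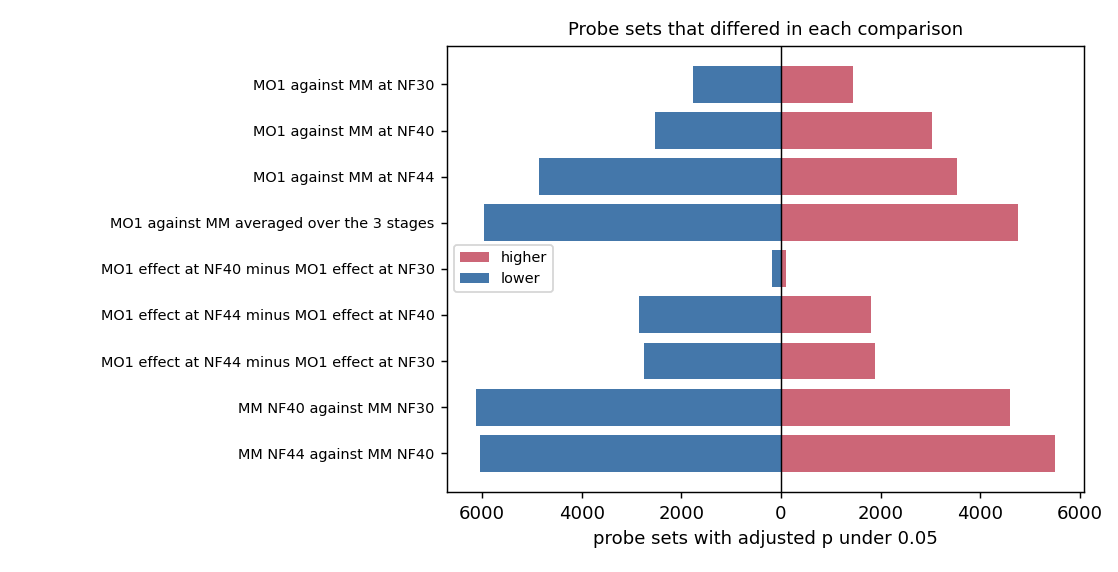
Numbers of probe sets with an adjusted p under 0.05 (horizontal axis) that were higher or lower in each comparison, drawn as bars to either side of zero. MO1 against MM gave 3211 at NF30, 5549 at NF40 and 8381 at NF44, and the difference between the NF40 and NF30 effects gave 264.

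The MO1 effects of the 3 stages overlapped in part. Of the probe sets higher at NF30, 710 were also higher at NF40, where 134 would be shared by chance, and 915 were lower at both stages, against 137 by chance. Between NF40 and NF44 849 were higher at both (328 by chance) and 1024 lower at both (377 by chance), but 593 were higher at NF40 and lower at NF44 (451 by chance) and 147 lower at NF40 and higher at NF44 (274 by chance). At all 3 stages 277 were higher and 453 lower, where 15 and 20 would be by chance. Across all probe sets the log2 changes of NF30 and NF40 had a Pearson correlation of 0.56, those of NF40 and NF44 of 0.22, and those of NF30 and NF44 of 0.16. The stages share no arrays in these counts, but they share one estimate of the spread.

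Tests of the difference between stages named genes whose MO1 effect differed between stages. Tff3.2.S, sftpc.S and pdia2.L were at 6.38, 12.3 and 0.00525 in MM at NF30, where little fall could show. Their differences therefore mostly restate the falls at NF40. The NF40 effect was more negative than the NF30 effect for tff3.2.S (-4.25 ± 0.37, limma adjusted p = 2.4e-05), sftpc.S (-4.21 ± 0.62, adjusted p = 0.0041) and pdia2.L (-4.13), and more positive for ucp1.S (4.90), epgn.L (2.33) and neurod1.S (2.07). Only 92 probe sets had a higher and 172 a lower effect at NF40 than at NF30. That total of 264 was 669 with replicates as a block within stages (356 and 313), 153 with a pseudocount of 1, 164 without the dimmer 50 percent of probe sets and 143 with only the compared arrays, and it was 157, 116 and 570 without MM replicates 1, 2 and 3 of NF40, and 147 and 140 without MO1 replicates 1 and 3 of NF40. Progenitor transcription factors had 5 of 27 genes with a lower effect at NF40 and none with a higher one (12 and 0 alone; camera adjusted p = 6.9e-13, adjusted p = 0.053 with an estimated correlation).

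From NF40 to NF44 the MO1 effect moved down most for cela1.5.L (-8.51 ± 0.18, limma adjusted p = 4.5e-14), pglyrp1.S (-8.06) and atp4b.L (-7.42), and up for g6pc1.2.S (4.15), nppa.L (3.37) and myog.S (3.29). Cela1.5.L, pglyrp1.S and atp4b.L were at 19.5, 31.1 and 27 in MM at NF40, where little fall could show. Their differences therefore mostly restate the falls at NF44. Exocrine enzymes had 13 of 24 genes with a lower effect at NF44 and none with a higher one (15 and 0 alone; camera adjusted p = 2.6e-09, and 0.034 with an estimated correlation). Hormone genes had 7 of 13 lower and none higher (7 and 0 alone; camera adjusted p = 5.6e-05, 0.032 with an estimated correlation), but the list lost its call without the dimmer 50 percent of probe sets (adjusted p = 0.35). Retinoic acid genes had 4 of 18 higher and none lower (8 and 1 alone; camera adjusted p = 0.0012, and 0.032 with an estimated correlation). Over all probe sets 1815 had a higher and 2849 a lower effect at NF44 than at NF40, so 38.9 percent were higher. Quantile normalization gave 2870 higher and 2804 lower (50.6 percent) and median centring 3037 and 2576 (54.1 percent). Against NF30 the effect at NF44 was higher for 1884 and lower for 2742 probe sets, which is 40.7 percent higher, and median centring gave 2678 and 2542 (51.3 percent). Cela1.5.L led the falls in this last test as well (-8.47 ± 0.18).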

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

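The tests for a delay of development, a share of endoderm and a share of liver were written after their results had been seen, while the other tests were written before their values were computed, with the FoxO and glucocorticoid lists chosen because of the pattern they test. After the values were known, the spreads of these 5 tests were widened to the arrays of both groups, and the endoderm test was split into a heart part and a muscle part. Every pattern below was noticed in these data, so any biological reading of it is a hypothesis.

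Exocrine enzyme and gastric proton pump genes stayed low in MO1 foreguts at NF44. If late genes all rose with the same time course, a general delay would hold them back alike. In MM, 9 smooth muscle genes rose from NF40 to NF44. In MO1 they reached a median share of 0.766 ± 0.152 of that rise (mean ± SD of 3 arrays). The 20 exocrine and pump genes that rose in MM reached 0.0619 ± 0.122. The difference of 0.7 (SD 0.0474 over the arrays of both groups) argues against a delay that gives both sets equal shares. It cannot exclude a general delay, because genes with different time courses would reach unequal shares under it. How the rises ran between NF40 and NF44 was not measured. Only genes that rose in MM entered this comparison. Some genes that fell in MM over this step were higher in MO1 at NF44, which a delay would also give. Over its probe sets darmin.L changed by -5.87 to -4.15 in MM and was 2.49 to 3.03 higher in MO1. Sox11.S changed by -1.91 to -1.75 in MM and was 1.63 to 1.7 higher in MO1. How many falling genes went either way was not counted. A delay of the endoderm alone may also remain. Under quantile normalization 98.6 percent of the median change of the exocrine list was kept (-3.20 in place of -3.25). No array median lay more than 0.19 from the median of arrays on the log2 scale. Rescaling could thus remove little of the change, and the scaling applied by the authors is not known here. A candidate explanation is that the acinar and gastric programmes could depend on the targeted gene, but this was not tested here.

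Skeletal muscle genes were higher and heart genes lower in MO1 foreguts at NF30. A smaller share of endoderm would by itself raise all other tissues. Alone it cannot give the fall of heart genes, since the median change of the heart list was -0.891 (SD 0.221 over the arrays of both groups). A smaller share beside a separate change of heart genes was not excluded. For the rise of skeletal muscle a smaller share of endoderm stays open. The median of that list exceeded that of heart by 1.89, less than 2 times the SD of 1.22 of that difference. Skeletal muscle carried along in varying amounts at dissection may explain the muscle part, and this stays open: deviations of 15 abundant muscle genes had a mean correlation of 0.64 within groups. Their level had an SD of 1.32 between replicates, beside a change of 1.83, and whether carried-along tissue could also account for the heart genes was not tested.

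Pck1, g6pc1, sds and ucp1 were higher in MO1 foreguts at NF40 and NF44, with medians of 1.44, 4.12 and 4.42 over 11 genes at NF30, NF40 and NF44, and 6, 11 and 10 of them called. The median of the other 46 liver genes was -0.22 at NF40 (SD 0.165) and 0.214 at NF44. A larger share of liver alone would raise those genes too, so the NF40 value argues against it as the only cause there. At NF44 the median was also far below the 4.42 of the pattern genes, but no spread was computed at that stage. A larger share beside a separate fall of other liver genes was not excluded. FoxO target activation may fit, as the lower of the medians of 25 target genes at NF40 and NF44 was 0.46 (0.46 and 0.58), with 12 and 13 higher, 0 and 2 lower, camera adjusted p of 9.7e-06 and 8.3e-06, and 0.033 and 0.045 with an estimated correlation. These camera p-values were adjusted over the 6 lists written after the data had been examined. The motile cilia and gluconeogenesis lists had the same camera adjusted p of 0.033 and 0.045 with an estimated correlation. The FoxO calls under that setting may therefore depend on those lists. At NF30 the FoxO median was 0.41 with 7 higher and an adjusted p of 1.4e-05, 0.093 with an estimated correlation. A glucocorticoid response stays open, with a lower median of 0.079 at NF44, 0.31 at NF40, camera adjusted p of 0.00044 at NF40 and 0.039 at NF44 (0.044 and 0.22 with an estimated correlation), and 2, 8 and 7 of 20 genes higher and 0, 1 and 1 lower at NF30, NF40 and NF44.

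Labels were also exchanged between arrays to ask whether other assignments of the labels can give as many calls. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and in each of these contrasts only 1 split, the real one, gave as many calls. Real values and the highest of the other splits were 3211 and 9 at NF30, 5549 and 1 at NF40, 8381 and 9 at NF44, 10712 and 2 for MM NF40 against NF30, and 11563 and 0 for MM NF44 against NF40. Over 100 splits within stages only 1 split, the real one, was as large for the mean over stages (10720 against 4212 for the highest other). Splits that kept or exchanged a whole stage were drawn here too, so this share also depends on the draw. For the difference of NF44 from NF40 only 1 split, the real one, was as large (4664 against 3746). For NF44 from NF30 3 splits were as large (4626 against 5102), and for NF40 from NF30 6 were (264 against 2517). The other splits as large, 2 and 5, all kept or exchanged the labels of a whole stage, so they reflect the structure of the samples. How many such splits were drawn sets these shares, so chance was not excluded for any of these differences. Splits that mixed labels in every stage gave at most 1, 1 and 43 in the same order, below the real values. The splits took no account of the resemblance of arrays with the same replicate number.

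Several genes had an MO1 effect that differed between stages. In MM at NF30, tff3.2.S, sftpc.S, pdia2.L, cldn18.L and cel.2.S were at 6.38, 12.3, 0.00525, 2.66 and 1.94, where little fall could show. Between NF40 and NF30 264 probe sets differed. The effect moved by -4.25 for tff3.2.S, -4.21 for sftpc.S, -4.13 for pdia2.L, -4.08 for cldn18.L and -3.89 for cel.2.S. It moved by 4.90 for ucp1.S, 2.64 for ucp1.L, 2.33 for epgn.L, 2.11 for cd53.S and 2.07 for neurod1.S. The call of ucp1.L (adjusted p = 0.029) was lost without any 1 of the 12 arrays other than MM replicate 3 of NF30 or of NF40 (0.053 to 0.073) and with a floor at the 25th percentile (0.25). The call of cd53.S (adjusted p = 0.049) was kept only without MM replicate 3 of NF30, MM replicate 1 of NF40 or MO1 replicate 2 of NF40, and was lost without any other array (0.059 to 0.12) and with replicates as a block across stages (0.055).

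Between NF44 and NF40 4664 probe sets differed. In MM at NF40, cela1.5.L, pglyrp1.S, atp4b.L, cela2a.L and atp4b.S were at 19.5, 31.1, 27, 9.57 and 0.00729, where little fall could show. The effect moved by -8.51 for cela1.5.L, -8.06 for pglyrp1.S, -7.42 for atp4b.L, -6.92 for cela2a.L and -6.72 for atp4b.S. It moved by 4.15 for g6pc1.2.S, 3.67 for frrs1.S, 3.52 for acsbg2.L (-0.20 to 3.52 over its 3 probe sets), 3.37 for nppa.L and 3.29 for myog.S. The list medians of this difference were -2.30 for exocrine enzymes, -0.83 for hormones (camera adjusted p = 5.6e-05, but 0.35 without the dimmer 50 percent of probe sets) and 0.49 for retinoic acid genes.

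Between NF44 and NF30 4626 probe sets differed. In MM at NF30 the mean log2 level was 5.14 for the exocrine list and 5.09 for the hormone list. The scale cannot go below 4, so both lists had little room to fall at NF30. The effect moved by -8.47 for cela1.5.L, -8.18 for pglyrp1.S, -7.31 for atp4b.L, -7.08 for ctrl.L and -6.91 for cela2a.L. It moved by 5.61 for ucp1.S, 4.80 for g6pc1.2.S, 4.57 for ucp1.L, 4.46 for pck1.S and 4.31 for mmp1.S, whose adjusted p was 0.032. The call of mmp1.S was kept without MM replicate 3 or MO1 replicate 1 of NF30 and without MO1 replicates 1 or 2 of NF44, and was lost without any other array (0.051 to 0.082). The list medians of this difference were -3.39 for exocrine enzymes (18 of 24 lower, 18 alone, camera adjusted p = 3.1e-15, 0.0098 with an estimated correlation), -1.06 for hormones (7 of 13 lower, 7 alone, 1.9e-06, 0.0098, but 0.14 without the dimmer 50 percent of probe sets) and 0.58 for retinoic acid genes (7 of 18 higher and 1 lower, 8 and 1 alone, 0.00072, 0.01).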

How the results depend on the processing

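All alternatives were planned before the data were examined. None was run for rfx6, which was not analysed here. The cause of a moved value was not tested.

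Of the count results, 220 stayed the same under an alternative and 35 moved past the margin set for counts (more than 1.5 times higher or lower). Requiring a change of at least 1 on the log2 scale gave 323 in place of 3211 at NF30, 1373 in place of 5549 at NF40, 2183 in place of 8381 at NF44 and 575 in place of 10720 for the mean over stages. The same requirement gave 2361 for the NF44 effect minus the NF40 effect, 2277 for the NF44 effect minus the NF30 effect, 2979 for MM NF40 against NF30 and 2894 for MM NF44 against NF40. Fitting only the compared arrays gave 1048 at NF30. The count for the NF40 effect minus the NF30 effect went from 264 to 203 with the requirement of a change of at least 1, which is inside the margin, but became 153 with a pseudocount of 1, 164 without the dimmer 50 percent of probe sets, 143 with only the compared arrays and 669 with a replicate block within stage.

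Leaving out each array in turn gave 1699 to 2705 probe sets at NF30, 3057 to 4668 at NF40, 6545 to 8352 at NF44 and 9653 to 10839 for the mean over stages. It gave 116 to 570 for the NF40 effect minus the NF30 effect, 3534 to 4900 for the NF44 effect minus the NF40 effect and 3699 to 4853 for the NF44 effect minus the NF30 effect. For MM foreguts the ranges were 8456 to 9850 for NF40 against NF30 and 9432 to 10132 for NF44 against NF40.

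The list test depended most on how correlation within a list was handled. With camera and an estimated correlation, 1 list in place of 5 was past the threshold at NF30, 0 in place of 10 at NF40, 4 in place of 15 at NF44 and 1 in place of 12 for the mean over stages. For the differences between stages it left 0 in place of 11 (NF40 minus NF30), 3 in place of 12 (NF44 minus NF40) and 3 in place of 11 (NF44 minus NF30). For MM stages it left 0 in place of 10 (NF40 against NF30) and 2 in place of 8 (NF44 against NF40), where leaving out the dimmer 50 percent of probe sets left 4. Fry called 3 lists at NF30 and 3 for the NF40 effect minus the NF30 effect. A replicate block within stage brought the epidermis list at NF44 from an adjusted p of 0.066 to 0.048, and it left skeletal muscle and cell cycle without a call in the NF40 effect minus the NF30 effect (9 lists in place of 11). Blocked fits changed no other list call. Quantile normalization left 4 lists without a call at NF44: intestine and kidney (both with an adjusted p of 0.075), cell cycle (0.053) and Hedgehog (0.058). Without the dimmer 50 percent of probe sets, secretory machinery (0.093) and kidney (0.35) lost the call at NF44, hormones lost it in the NF44 effect minus the NF40 effect (0.35) and in the NF44 effect minus the NF30 effect (0.14), and endocrine transcription factors gained one at NF40 (0.002).

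For the 886 gene results eligible for naming, 16726 comparisons with an alternative kept the same call, 196 gained a call, 732 lost it, and 0 were reversed.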

Other observations

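All lists in this part were written after the data had been seen, and no list here was planned. Their camera p-values come from the same arrays, so they describe the shifts and give no independent support.

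Genes of motile cilia and of ionocytes moved strongly in dissected foreguts of both kinds. Of 34 motile cilia genes, 29 were higher and none lower in MO1 at NF40 (median 1.5, camera adjusted p = 3.1e-23, 0.033 with an estimated correlation), and 33 were lower and none higher at NF44 (median -2.60, camera adjusted p = 1.7e-25, 0.045 with an estimated correlation). At NF30 3 were higher and 2 lower (12 and 2 over the list alone), with a median of 0.51 and a camera adjusted p of 2.9e-05, 0.29 with an estimated correlation. Their mean log2 level was 7.05 ± 0.44 in MM and 8.38 ± 0.09 in MO1 at NF40, and 8.58 ± 0.06 in MM and 6.28 ± 0.13 in MO1 at NF44. Of 14 ionocyte proton pump genes all 14 were higher at NF40 (median 2.3, camera adjusted p = 1.5e-10, 0.066 with an estimated correlation), 2 were lower and none higher at NF44 (camera adjusted p = 0.66), and 1 was higher at NF30 (4 over the list alone), with a median of 0.82 and a camera adjusted p of 0.00023, 0.29 with an estimated correlation. The level of the ionocyte genes at NF40 was 8.13 ± 1 in MM and 10.2 ± 0.22 in MO1, so the MM arrays differed widely among themselves.

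A list of gluconeogenesis and related genes was not used as a test, since 11 of its 18 members are the pck1, g6pc1, sds and ucp1 genes that had been seen to rise. Integrated stress response genes were not shifted at any stage, with 2 of 16 higher and 3 lower at NF30, 2 and 4 at NF40, 5 and 8 at NF44, and camera adjusted p of 0.68, 0.71 and 0.66. The log2 ratio of the 3' to the 5' control probe sets of ef1a was -0.89 ± 0.19 in MM and -0.61 ± 0.05 in MO1 at NF30, -1.17 ± 0.18 in MM and -0.97 ± 0.14 in MO1 at NF40, and -0.99 ± 0.21 in MM and -1.31 ± 0.09 in MO1 at NF44. The same ratio of gapdh in MM and MO1 was 0.764 ± 0.096 and 0.757 ± 0.033 at NF30, 0.682 ± 0.046 and 0.609 ± 0.077 at NF40, and 0.725 ± 0.068 and 0.68 ± 0.091 at NF44. For actin it was 3.7 ± 0.16 and 3.66 ± 0.029 at NF30, 3.88 ± 0.067 and 3.74 ± 0.05 at NF40, and 3.81 ± 0.22 and 3.81 ± 0.18 at NF44.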
